A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

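The series holds 8 arrays of total RNA from Saccharomyces cerevisiae grown to mid-log phase: 7 aneuploid strains and 1 wild-type sample (WT1) in Cy5, each against the wild-type RNA WT2 in Cy3, per the labels. No dyes were swapped, so a dye effect common to all arrays stays in each ratio and cancels only in differences from WT1. The arrays lay on 1 slide with 1 scan time, with A2, A3, A9 and A10 in the first row of the slide and A13, A14, A15 and WT1 in the second. Nothing states that the samples came from separate cultures, so p-values measure only the spread between these samples, part of which may be technical.

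Spots were quantified by Agilent Feature Extraction 10.5.1.1, per the file headers. Median spot and local background intensity of both channels were used as deposited, without normalization per the file headers. The processed signal intensity of both channels was background-subtracted and dye-normalized, per the file headers. The log10 ratio of red over green processed signal is also given, per the file headers. The deposited value table holds log2 ratios of red over green, which matched the log10 ratios on a log2 scale within 5e-04 on each array and had a median of 0 in each column, so its scale, direction and centring were settled. Its number of columns that belong to no sample was 0.

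The files as used here hold median spot signals, which took the place of the mean signals named in the planned design. Background was corrected with normexp (offset 50) and ratios were normalized within each array by loess in limma 3.58.1 under R 4.3.3 with matrixStats 1.5.0, with weight 0 for the 536 control spots. Spots with outlier flags were left out, saturated spots were kept, so that the ratio of a gene saturated in a strain is a lower bound, and the 2 spots of each gene were averaged. The array has 1 probe per gene, so no rule for several probes was needed. Of 6256 genes, 5756 took a symbol from a table of assembly R64, used for names and neighbours only because the array design follows an older build, and 500 kept the name in the file. The 6126 genes well above background in either channel on at least 2 arrays were tested, and 53 of them lacked a value on some array. The fold of a gene not well above background is a lower bound, taken per channel after Aquantile scaling from the lowest signal among genes well above background.

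Strains served as replicates of the aneuploid group, and the lone WT1 array was assumed to vary like them. limma's lmFit and eBayes tested strains minus WT1, two-sided, with Benjamini-Hochberg adjustment, on the log2 ratios and again after subtracting on each array the median of the gene's chromosome. A chromosome stood apart when its median was at least 0.3 in size and outside all of 10000 random gene lists matched on intensity in 10 bins. Folds of chromosomes are relative to the median of the chromosomes that did not stand apart on that array. In the strains this median lay between -0.15 in A10 and -0.0033 in A13, and on WT1 at -1e-04. Intervals of 95% for chromosome medians came from 1000 bootstrap draws of genes and those of lists from 500, and cover the spread over genes only. Of 33 gene lists, 31 were tested with camera, a competitive test that compares a list with all other genes, and adjusted over the lists. The 4 genes of the 2-micron plasmid were not analysed here, since 0 of them matched a probe, and the marker genes were read gene by gene. A list needed at least 4 measured genes.

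The stress score was compared with the share of genes on chromosomes that stood apart in either direction, all raised at the threshold of 0.3, by exact permutation over 7 strains. Similarity was the covariance of chromosome-centred ratios over genes. The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each limma result, up to 12 genes in each direction past the threshold with the same sign in 7 of 7 strains, or, with fewer than 10, the genes of smallest p up to 10. It also took up to 4 genes of smallest p per list, the 3 highest and 3 lowest genes of each strain relative to WT1, and any gene of the marker and mating lists. MATALPHA1, MATALPHA2, HMRA1, the Haa1 targets, HAA1 and HAP4 were named after their values were seen, as was the selection of genes described from those the rule allowed.

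The steps were tested on simulated data. With 200 of 6126 genes changed in 20 simulations of 7 strains against 1 WT1 array, limma recovered 2.76% of genes changed by 0.5, 41.0% by 1 and 84.2% by 2 on the log2 scale, with 4.7 false calls per run. Against WT2 it recovered 74.3, 94.9 and 99.5%, with 8.95 false calls. No error shared through WT2 or the dyes was simulated, so the real arrays may give more false calls against WT2. Camera called a list of 30 genes shifted by -0.5 in 100% of simulations and 1.5% of unchanged lists. The simulated genes varied independently, whereas the estimated correlation within real lists reached 0.95, for the a-specific genes. The simulation therefore says nothing about false calls in correlated lists. A shift of 0.6 on chromosome VI of the WT1 array, with 128 genes, was found as the 1 chromosome past the threshold. Alternatives covered centring on the mode of the ratios, Agilent's processed signals, no background subtraction, no and strict signal filters, the deposited table, WT2 as the control, slide row as a block, eBayes with trend and robust, other thresholds, fry in place of camera, an estimated correlation and leaving out each strain. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.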

Results

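RNA from 7 aneuploid strains of Saccharomyces cerevisiae (budding yeast cells with an abnormal number of chromosomes), named A2, A3, A9, A10, A13, A14 and A15, was hybridised to 2-colour Agilent arrays. Each strain was labelled with Cy5 and set against the same Cy3-labelled wild-type RNA, WT2. An eighth array carried a second wild-type RNA, WT1, against WT2, and served as the control. All cells were grown to mid-log phase. Each of the 8 arrays measured 6256 genes with 2 spots per gene, of which 6126 passed the signal filter. Median red signals lay between 539 and 1532 over a background of 36 to 37, and median green signals between 364 and 614 over 21 to 22.5. Between 94.2 and 98.0% of genes were well above background in red and between 92.7 and 97.1% in green. Duplicate spots of a gene differed with an SD of 0.0525 to 0.0701 on the log2 scale. The number of arrays limits the precision: each strain was measured on 1 array, so values per strain have no replicate. The labels do not say whether A2 and A3 share a parent, and they count as 2 of the 7 strains throughout.

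The labels do not say which chromosomes each strain carried in excess, so the first comparison asked which chromosomes differed from wild type in transcript level. Chromosome II was higher in A2, A3, A9 and A15, with median log2 ratios over WT2 of 0.66, 0.73, 0.64 and 0.49. Chromosome XII was higher in A2 at 0.59, in A3 at 0.50 and in A10 at 0.32, and chromosome I in A3 at 0.67 and in A13 at 0.59. A10 also showed higher chromosomes III at 0.67, XI at 0.64 and XV at 0.58. In A9 the medians of chromosomes XIII and XVI were 0.70 and 0.55, and in A14 those of chromosomes IX and XVI were 0.79 and 0.75. A15 had higher chromosomes X at 0.46 and XI at 0.64.

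In all, 18 of 112 pairs of strain and chromosome stood apart from intensity-matched random gene lists by at least 0.3, and 18 of these were higher. None of the 16 chromosomes stood apart on the WT1 array, whose largest chromosome median was 0.0358 in size. Relative to the other chromosomes of the same strain, the raised chromosomes were 1.38 to 1.76 times as high, with a median of 1.65. Among the brighter genes of these chromosomes the median was 1.80. At least 77.8% of the genes on each raised chromosome had a ratio above 0, and the left and right arms differed by at most 0.206. Raised chromosomes held 26.0% of measured genes in A10, 22.7% in A9, 18.5% in A15, 17.3% in A3, 15.7% in A2, 11.5% in A14 and 1.67% in A13. In A13, chromosomes II, XI, VIII and XIII lay below the threshold at 0.27, 0.26, 0.23 and 0.19, beside chromosome I at 0.59. In A15, chromosomes IX, III and XII lay further below it at 0.12, 0.11 and 0.10, yet above all their matched random lists. They were at 1.15, 1.14 and 1.13 times the chromosomes of A15 that did not stand apart. With a threshold of 0.2, chromosomes II, VIII and XI of A13 also stood apart as higher and chromosome IV of A10, at -0.22, as lower, and with 0.45 chromosome XII of A10 did not stand apart. That chromosome IV was at 0.948 times the chromosomes of A10 that did not stand apart, which themselves lay at -0.15. At 0.3, chromosome II of A13 was added by mode centring, II and XI of A13 by Agilent's processed signals, and these and the lower IV of A10 by the deposited table. With the ratios used here and 0.3, 0 chromosomes were lower than wild type, and 6 stood apart in no strain.

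**Figure D1:**
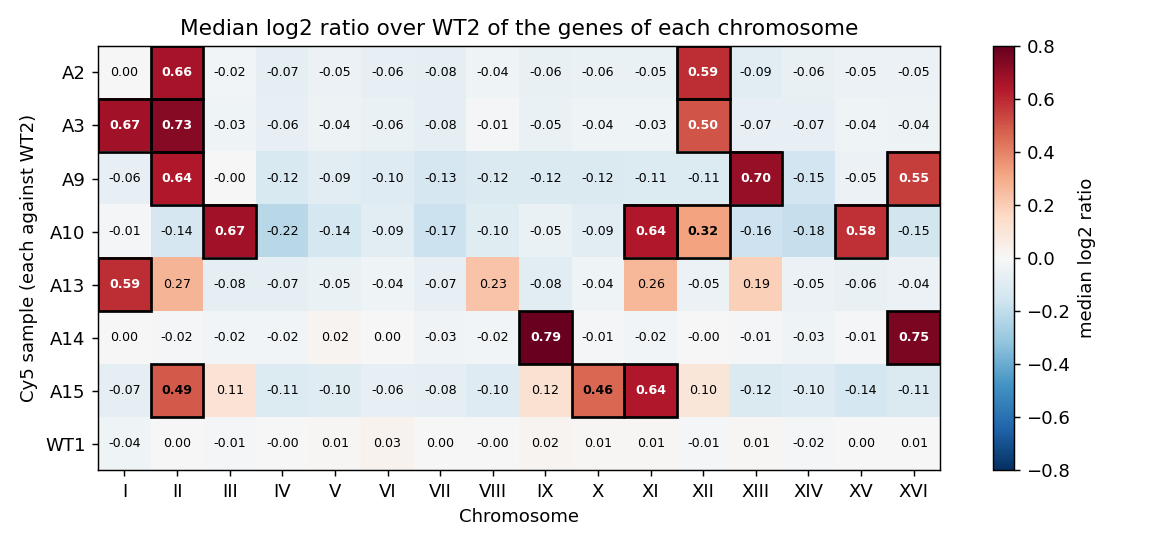
Median log2 ratio over WT2 of the genes of each chromosome (columns) on each array (rows), with the value printed in each cell and black frames around the 18 pairs that stood apart. The medians of the WT1 array are at most 0.0358 in size, and the framed medians lie between 0.32 and 0.79.

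The next comparison asked which genes the 7 strains changed together relative to WT1, whatever chromosomes they carried. No single gene passed the test. The genes nearest to it included LYS9, an enzyme of lysine synthesis, at a log2 difference of -0.73 (SE 0.193, n = 7 strains against 1 array), and NDJ1, which acts at meiotic telomeres, at -0.81 (SE 0.238). GLT1, glutamate synthase, was at -0.68 (SE 0.229), and SIS1, a chaperone of the Hsp40 family, at -0.58 (SE 0.206). These 4 genes had the same sign in 7 of 7 strains and were also lower against WT2 relative to their chromosomes (LYS9 -0.53, NDJ1 -0.81, GLT1 -0.41, SIS1 -0.35).

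For 6 other genes of small p the WT1 array itself lay away from WT2. ISA1, which matures iron-sulfur proteins, was higher in the strains, with WT1 at -1.10 against WT2. NAR1, also of iron-sulfur assembly, had -0.85 (SE 0.188) with WT1 at 0.83, and RPS4A, a ribosomal protein gene, -0.94 (SE 0.261) with WT1 at 0.80. The differences of TRM13 and EMC4 were -0.52 and -0.46, with WT1 at 0.47 and 0.36, and that of the septin gene CDC3 relative to its chromosome was -0.61 (SE 0.189), with WT1 at 0.42. TEX1 had -0.48, with the strains at -0.27 over WT2 and WT1 at 0.21. Relative to their chromosomes, SFG1, a regulator of filamentous growth, had -0.99 (SE 0.282), APA1 -0.70 (SE 0.183) and RPS9B -0.60 (SE 0.175), with WT1 at 0.11, 0.08 and 0.08 over WT2. limma called 0 genes higher and 0 lower at an adjusted p under 0.05, with 32 of 6126 genes at an unadjusted p under 0.05 where 306 were expected by chance. After subtraction of each chromosome's median it also called 0 and 0, with 53 genes at an unadjusted p under 0.05. With so few small p the test was conservative, so 0 calls do not show that no gene changed in common. Over genes, log2 ratios had an SD of 0.156 on WT1 but 0.271 to 0.708 in the strains, although the test assumed that they vary alike. Against WT2 alone, which leaves out the spread of wild type, limma called 143 genes higher and 188 lower, and 319 higher and 375 lower relative to their chromosomes. In that last fit the 4 genes named first and SFG1, APA1 and RPS9B passed, with adjusted p of 0.00872 for LYS9, NDJ1, SFG1, APA1 and RPS9B, 0.0135 for GLT1 and 0.0152 for SIS1. TEX1 passed against WT2 before that subtraction (adjusted p 0.0407) and not after it (0.0515).

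Gene lists fixed in advance asked whether known pathways moved as groups. Ribosomal protein genes were lower than in WT1 in 7 of 7 strains, by a mean log2 difference of -0.20, with 103 of 132 members below 0. Their chromosome-centred median over WT2 was -0.21 ± 0.11 (SD, n = 7) against 0.01 on WT1. Heat shock chaperone genes were lower in 7 of 7 strains, by -0.17 (18 of 24 members), with medians of -0.15 ± 0.11 (SD, n = 7) against 0.14 on WT1. Without chromosome centring the chaperone medians over WT2 were 0.01 in A9 and 0.08 in A10, lower only against WT1 at 0.13. Amino acid biosynthesis genes were lower in 7 of 7 strains, by -0.16 (29 of 44 members), and in 6 of 7 relative to their chromosomes. Their chromosome-centred medians were -0.10 ± 0.17 (SD, n = 7) against 0.04 on WT1. They lay below matched random lists in A9 (-0.40), A14 (-0.24) and A13 (-0.13), within them in A2, A3 and A10, and above them in A15 (0.07). Without centring the A15 median was 0.02 over WT2, lower only against WT1 at 0.05. Higher as groups were the seripauperin genes, a cell wall mannoprotein family near the telomeres, by 0.40 (24 of 24 members, 7 of 7 strains), and the cell wall integrity genes, by 0.39 (15 of 16 members, 7 of 7 strains). In A9 and A13 the seripauperin medians over WT2 were -0.0559 and -0.065, so they were higher only because WT1 lay at -0.117.

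The iron regulon was higher by 0.33, with 15 of 16 members above 0 and 5 of 7 strains above WT1, and the general stress genes by 0.30, with 43 of 53 members and 4 of 7 strains. The a-specific genes, expressed in cells of mating type a, were lower by -1.78 (7 of 7 members, 6 of 7 strains), and the haploid-specific genes, repressed in a/alpha diploid cells, by -0.69 (11 of 11 members, 7 of 7 strains). In A14 the haploid-specific median over WT2 was 0.01, lower only against WT1 at 0.10. Adjusted p of limma's camera with its preset correlation of 0.01 was 3.35e-13 for the ribosomal proteins, 4.92e-15 for the seripauperins, 0.000536 for the a-specific genes and 0.000626 for amino acid biosynthesis. It was 0.00146 for the chaperones, 0.00525 for the iron regulon and for cell wall integrity, 0.0068 for the haploid-specific genes and 0.0233 for general stress. None of these 9 calls held with an estimated correlation. For the ribosomal proteins the adjusted p = 0.50 with an estimated correlation, for the chaperones the adjusted p = 0.453 with an estimated correlation, and for the other 7 lists it was 0.761 or 0.956. In each of the 31 lists tested, 0 members rose and 0 fell over all genes tested by limma, and 0 adjusted over the list alone.

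Among ribosomal protein genes, RPS24A was at -0.52 (SE 0.196) and RPL22B at -0.68 (SE 0.271). Of the chaperone genes, MDJ1 was at -0.40 (SE 0.166), BTN2 at -0.84 (SE 0.391) and AHA1, a cochaperone of Hsp90, at -0.57 (SE 0.279). HIS1 of histidine synthesis was at -0.70 (SE 0.348) and ASN1, asparagine synthetase, at -0.55 (SE 0.387). PIR1 and HSP150, a pair of cell wall proteins, were at 0.86 (SE 0.371) and 0.89 (SE 0.52). HMX1, heme oxygenase, was at 0.58 (SE 0.289), FET3, the iron-uptake ferroxidase, at 0.61 (SE 0.471), and PAU2 of the seripauperins at 0.39 (SE 0.207). In the general stress list HSP26 and UBI4, polyubiquitin, were at 0.89 (SE 0.579) and 0.83 (SE 0.683). The seripauperin and ribosomal protein families hold near-identical copies that a probe may not separate, so single members are uncertain. The general stress call was lost without A9 (0.18), A10 (0.09), A13 (0.29) or A14 (0.29), and the iron call without A15 (0.18). Without A10 the haploid-specific difference was -0.30, and without A9 that of amino acid biosynthesis was -0.10, both still called. Without A9 and A10 the general stress difference turned to -0.10 and that of the haploid-specific genes was -0.24, neither called, while the a-specific genes were at -0.78, cell wall integrity at 0.23 and ribosomal proteins at -0.13, all still called. Without genes of raised chromosomes the haploid-specific call was lost (-0.79), and ribosomal proteins were at -0.31, chaperones at -0.32, amino acid biosynthesis at -0.27 and cell wall integrity at 0.21, all still called. With mode centring the general stress call was lost (0.36) and amino acid biosynthesis was at -0.11, still called. Relative to their chromosomes the chaperones differed from WT1 by -0.26, still called. Against WT2 the chaperones (-0.08, adjusted p 0.093 by camera) and the iron regulon (0.18, adjusted p 0.153) were not called, but relative to their chromosomes the chaperones were, at -0.16 (adjusted p 0.00378 by camera; adjusted p = 0.877 with an estimated correlation). On WT1 the seripauperin and iron medians were themselves at -0.12 and -0.15. Within the slide row that holds WT1, with A13, A14 and A15, general stress was at 0.12 and not called, the other 8 lists were called, and the means were -0.12 for ribosomal proteins, 0.62 for the iron regulon, -0.49 for a-specific and -0.27 for haploid-specific genes.

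The remaining 22 lists did not pass. Mean differences were 0.08 for ribosome biogenesis, 0.01 for RNA polymerase I and III, 0.07 for the proteasome, -0.04 for the ER unfolded protein response, 0.10 for oxidative stress and 0.07 for the DNA damage response. Of the metabolic lists, glycolysis was at -0.05, the TCA cycle at 0.23, the respiratory chain at 0.05, the mitochondrial ribosome at 0.07 and the mitochondrial genome at 0.13. Sulfur and methionine genes were at 0.06, phosphate starvation genes at -0.14, ergosterol synthesis at -0.0028 and glucose-repressed genes, among them PCK1 of gluconeogenesis at 0.78 (SE 0.646), at 0.17. The cell cycle lists were at -0.03 for G1/S, -0.02 for G2/M and 0.12 for M/G1, and histones at 0.02. Alpha-specific genes were at 0.68, meiosis and sporulation genes at 0.03 and stationary phase genes at 0.24. The smallest adjusted p among these 22 was 0.109, for the stationary phase genes.

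**Figure D2:**
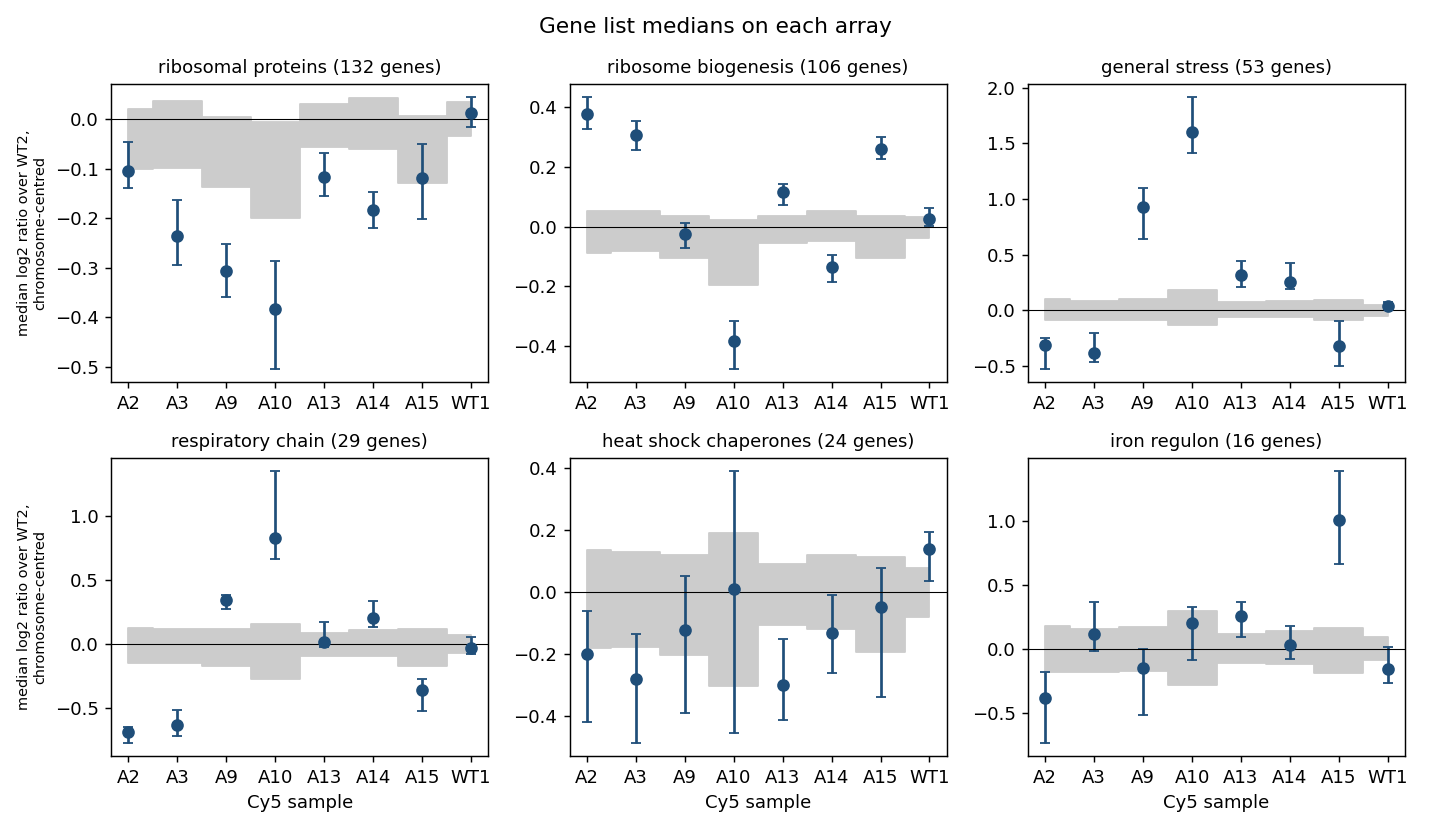
Chromosome-centred median log2 ratio over WT2 of 6 gene lists on each array, with bars for the 95% bootstrap interval over genes and grey bands for the central 95% of 10000 intensity-matched random lists. General stress genes lie at 1.61 in A10 and 0.93 in A9 and at -0.38 in A3, while ribosomal protein genes lie below 0 in each of the 7 strains.

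Values per strain were read to see how far each strain lay from wild type and which genes stood out. A10 had 515 genes at least 2-fold higher and 212 at least 2-fold lower than WT2, and A13 had 26 and 6. Counts were 259 and 76 in A9, 182 and 20 in A14, 164 and 67 in A2, 140 and 78 in A15, and 127 and 42 in A3. WT1 had 0 higher and 1 lower. Relative to their chromosomes the counts were 363 and 143 in A10, 16 and 6 in A13, 107 and 71 in A9, 36 and 25 in A14, 16 and 64 in A2, 38 and 74 in A15, and 7 and 36 in A3. With Agilent's processed signals all 8 counts moved by over 1.5 times, with genes past 2-fold per strain WT1 at 57, genes past 2-fold per strain A13 at 148 and genes past 2-fold per strain A10 at 1117. Of the genes past 2-fold higher, 94.5% lay on raised chromosomes in A3, 92.1% in A2, 85.2% in A14, 80.7% in A15, 76.4% in A9, 62.3% in A10 and 30.8% in A13.

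Genes that mark mating type set A9 and A10 apart. In A9 the a-specific genes STE2, the alpha-factor receptor, and BAR1 had log2 ratios over WT2 of -6.18 and -5.49. The alpha-specific genes STE3, MF(ALPHA)1 and MF(ALPHA)2, which encode the a-factor receptor and the alpha-factor precursors, stood at 4.66, 7.15 and 5.13, and MATALPHA1 at 2.95. WT2 was well above background for MF(ALPHA)1 on the A9 and A2 arrays alone, so its 7.15 rests on a reference signal near background and is approximate. The HMRA1 probe was not well above background in A9 and at least 13.8-fold lower than in WT2. In A10, STE2 and BAR1 were at -6.38 and -5.47, whereas STE3 was at 1.24, MF(ALPHA)2 at 0.19 and MATALPHA1 at -0.13. The haploid-specific genes HO, FAR1, STE18, GPA1 and RME1 were at -5.00, -4.54, -3.58, -3.50 and -2.28 in A10, with HMRA1 at 0.14. A2, A3 and A15 had lower values of ASG7, at -2.55, -2.39 and -2.08, of AGA1, the a-agglutinin anchor, at -1.93, -1.95 and -2.45, and of STE2, at -1.05, -1.04 and -1.84. On WT1 these genes lay between -0.03 and 0.30. Of the marker genes, LEU2 was at -1.07 in A9 and ADE2 at -0.90 in A2.

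**Figure D3:**
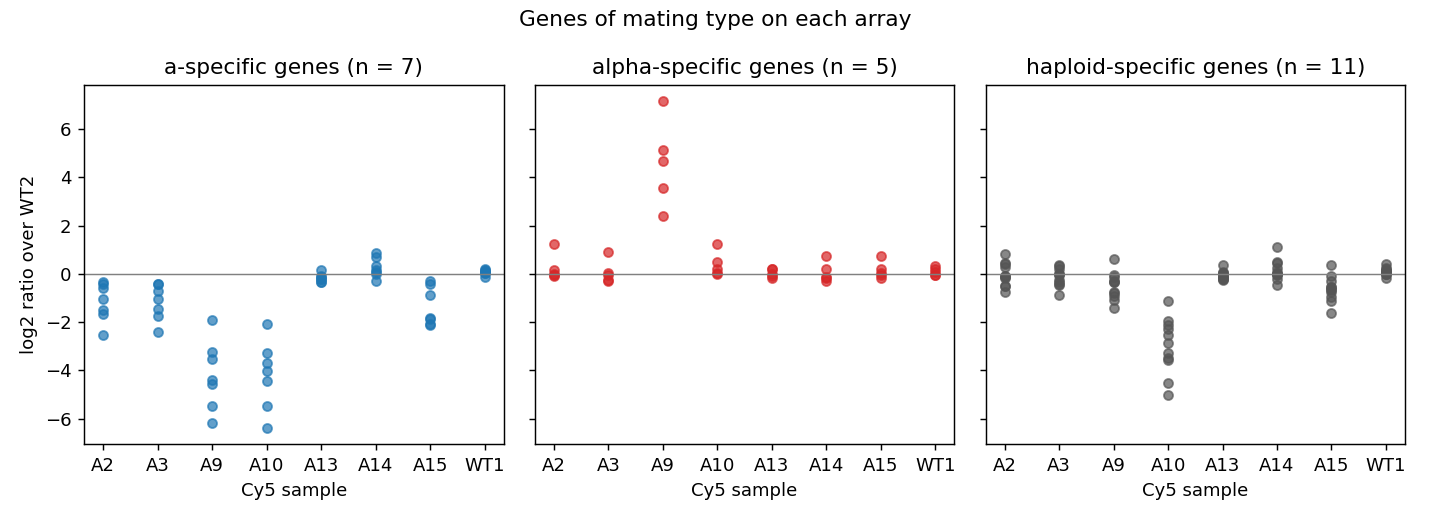
Log2 ratio over WT2 of 7 a-specific, 5 alpha-specific and 11 haploid-specific genes, 1 point per gene and array. In A9 the alpha-specific genes reach 7.15, and in A10 the haploid-specific genes reach -5.00.

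Outside the mating genes, RPS9A, a ribosomal protein gene, was at -2.44 in A2, -2.58 in A3, -1.36 in A9, -1.39 in A15, -1.28 in A13 and -0.74 in A10. In A14, where its chromosome XVI was raised, it was at 0.55, and at -0.24 relative to that chromosome and WT1. Chromosome XVI was raised in A9 too, where RPS9A was at -1.95 by that last measure. The mating gene FIG1 was at -1.35 in A2 and -1.60 in A3, and the cell wall gene CCW22 at 1.17 and 1.36. YRO2, TPO2, a polyamine exporter, and YGP1, a secreted glycoprotein, were at 4.57, 2.95 and 3.50 in A9 and at 3.50, 3.32 and 2.61 in A14. In A10 the stress gene HSP12 was at 4.80. CSS1 and the mannoprotein gene HPF1 were saturated in A10, at least 33.5-fold and at least 22.8-fold higher than in WT2. PHO84, the high-affinity phosphate transporter, was at -2.21 in A9, -3.09 in A10 and -2.90 in A14, and the glucose transporter HXT2 at -2.88 in A14. In A13, TMA10 and ALD4 were at 1.68 and 1.60 and ANB1 at -1.33. A15 had the siderophore transporter ARN2 at 2.08, the carbonic anhydrase NCE103 at 2.44, HPF1 at 2.49 and YGP1 at -2.59.

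A further comparison asked whether strains with more genes on raised chromosomes had a stronger stress profile. The score, the mean of general stress genes minus that of ribosome biogenesis genes relative to WT1, was 2.06 in A10 and 1.03 in A9, with 26.0 and 22.7% of genes on raised chromosomes. It was 0.46 in A14 and 0.30 in A13, with 11.5 and 1.67% of genes. In A2, A3 and A15 it was -0.85, -0.68 and -0.59, with 15.7, 17.3 and 18.5% of genes. Pearson's r was 0.37 (exact permutation p = 0.42, two-sided) and Spearman's rho 0.464 (exact permutation p = 0.302) over 7 strains, in a family of 1 relation. Without A13 and A10, the strains farthest from the median share, r was 0.249 (exact permutation p = 0.65) and rho 0.4 (exact permutation p = 0.517). For the stress score against altered gene share, r was -0.0768 with A10 alone left out. With a chromosome threshold of 0.2 it was 0.767 (exact permutation p = 0.0427), where the share of A10 includes its chromosome IV at -0.22, and 0.655 (exact permutation p = 0.103) counting raised chromosomes only. Both values also count chromosomes II, VIII and XI of A13, which that threshold adds.

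The last comparison asked how alike the chromosome-centred profiles of the strains were. A2 and A3 were the closest pair, with r = 0.862 across 6073 genes, which are not independent replicates, and chromosome I told them apart. With A2 and A3 averaged as 1 strain, limma called 0 genes and camera 10 lists. The lowest r among the 21 pairs was 0.0532. Mean covariance between strains was 0.0408, against 0.0129 between strains and WT1, which share WT2 in the same way, and 0.012 in 100 simulations of unchanged strains. The difference between the first and second of these was 0.0279, and 2 of 21 pairs lay below the mean with WT1. Mean correlations were 0.298 between strains, 0.231 with WT1 and 0.499 in the simulations. The covariance with WT1 rests on a single control array.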

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

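The tests of the explanations weighed here were chosen after the result was seen, as were the genes examined beyond the gene lists. A value was taken up when 1 strain of the 7 lay far from the other 6 relative to their whole range (Dixon's criterion), which chance does in about 1 in 20 groups. Of 107 quantities examined, 22 had such a strain, 12 with A10 and 8 with A9. Some genes were examined because they were extreme in a strain or were named after their values were seen, and many belong to the same lists, so an excess over the 5.35 of chance was built in and is no evidence of its own.

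Relative to their chromosomes, in A10 the haploid-specific median was -2.74, and HO was at -4.78, FAR1 at -4.45, STE18 at -3.49, GPA1 at -3.40 and RME1 at -2.11, each far below the other strains. In A9 the alpha-specific median was 4.77, with STE3 at 4.77, MF(ALPHA)1 at 6.60 over a reference near background, MF(ALPHA)2 at 5.26 and MATALPHA1 at 2.95, while the HMRA1 probe read -4.10 but was not well above background there, so that this gene was at least 13.8-fold lower than in WT2 and the value itself is not exact. A mixture of a and alpha cells would leave haploid-specific genes near the wild-type level, and the median of -2.74 in A10 argues against it. Without background subtraction the median in A10 was -2.85, which argues against dim spots as the source. That A10 may carry both mating-type alleles, as an a/alpha cell does, stays open. Over WT2, without regard to chromosome III, which was raised in A10, MATALPHA2 was at 0.47 with HMRA1 at 0.14, and relative to that chromosome and WT1 they were at -0.43 and -0.73. A9, with MATALPHA1 at 2.95, read only 0.57 over WT2 on the same MATALPHA2 probe, so the bound set for this test was wrong and the probe cannot settle it.

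Among other lists, A10 stood far above the other strains for cell wall integrity (0.86), meiosis and sporulation (0.30) and glucose-repressed genes (1.27). HSP12 and PCK1 were also far above the others in A10, at 4.89 and 1.62, as was CSS1, which was saturated there, so that its 5.12 is a lower bound. The marker gene median was far below the others in A9, at -0.44. SPI1 was far above the others in A9 at 2.76, ARN2 in A15 at 2.18 and SIS1 in A14 at -0.13.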

How the results depend on the processing

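The averaging of A2 and A3, leaving out A9 and A10, leaving out near-identical copies (picked by gene name), the slide row of WT1, and leaving out A10 or lowered chromosomes from the correlation were chosen after seeing the data. Of the results and settings compared, 1051 were labelled the same, 69 moved, 29 lost and 12 gained a call, and 3 reversed. What counted as the same depended on the kind of result. For counts, chromosomes and list medians per strain it was a change in size within a set limit, not a direction or a call. A single gene could be labelled the same by staying uncalled, so the 1051 alone do not measure robustness. With WT1 as the control limma called 0 genes under each alternative. Against WT2 the genes changed in aneuploid strains were 331 and the genes changed relative to their chromosome 694, and NAR1 in genes changed relative to their chromosome changed sign to 0.0724; WT1's own value is left out of that fit by construction. The number of lists called was 0 with an estimated correlation and 0 with fry, which does not compare a list with other genes, and 7 to 12 otherwise, with 8 to 10 when 1 strain was left out. The general stress list reversed to -0.0984 without A9 and A10 (adjusted p 0.567, range over its alternatives 0.000334 to 0.957), and was not called with mode centring or within the slide row of WT1, where its mean was 0.116. Haploid-specific genes lost their call without A9 and A10 (-0.24) and without genes of raised chromosomes (-0.79). Mode centring shifted arrays by up to -0.121, in A10, and cannot change values relative to chromosomes.

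Counts were higher with Agilent's processed signals and with the deposited table. In that order, and then relative to chromosomes where that moved them, genes past 2-fold per strain A2 numbered 501, 496 and 80, genes past 2-fold per strain A3 388, 388 and 43, genes past 2-fold per strain A9 725, 708 and 178, genes past 2-fold per strain A14 458, 447 and 61, and genes past 2-fold per strain A15 528, 519 and 112. For the other arrays, with the first 2 alone, genes past 2-fold per strain A10 numbered 1117 and 1112, genes past 2-fold per strain A13 148 and 146, and genes past 2-fold per strain WT1 57 and 52. Several choices differ at once in both sets of signals and the cause was not tested; the fall relative to chromosomes follows from subtracting raised chromosomes. For the stress score against altered gene share, r was 0.767 (exact permutation p = 0.0427) with a threshold of 0.2, which counts chromosome IV of A10 at -0.22, and 0.655 (exact permutation p = 0.103) counting raised chromosomes only. It was -0.0768 (exact permutation p = 0.897) without A10, for which the cause was not tested. The 18 raised chromosomes stayed so in each alternative except the threshold of 0.45, which left 17. Others were added: II of A13 with mode centring, II and XI of A13 with Agilent's processed signals, these and the lower IV of A10 with the deposited table, and these and VIII of A13 with a threshold of 0.2. The brightest-probe alternative was not run, since the array has 1 probe per gene. No paired analysis was possible because the replicate numbers only name different strains. Signals close to background compress ratios, which limits dim genes on raised chromosomes.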

Other observations

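Tests of the A13 chromosomes, of the ribosomal protein list, of HAP4 and of Haa1 were chosen after the result was seen, and the raised-chromosome tests before. Beyond the comparisons above, lists that did not pass the test over all strains had the following values per strain. The respiratory chain median relative to chromosomes was 0.83 in A10, 0.34 in A9, 0.20 in A14 and 0.01 in A13, and -0.69 in A2, -0.64 in A3 and -0.36 in A15, with -0.03 on WT1. TCA cycle genes lay at 1.14 in A10 and 0.50 in A9 and at -0.44 in A2, and mitochondrial ribosome genes at 0.28 in A10, 0.15 in A15, -0.02 in A14 and -0.34 in A2. Ribosome biogenesis genes were at 0.38 in A2, 0.31 in A3 and 0.26 in A15 and at -0.38 in A10. Histone genes were at -0.57 in A2 and -0.40 in A3, where they were at -0.20 and -0.0012 without subtraction of the chromosome medians, and at 0.27 in A14 and 0.21 in A13. Phosphate starvation genes were at -0.64 in A10, -0.40 in A14, -0.39 in A15 and -0.38 in A9. The iron regulon, called above, was at 1.01 in A15 and -0.39 in A2.

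YRO2, TPO2 and YGP1, high in A9 and A14, are targets of the weak-acid regulator Haa1, whose gene lies on chromosome XVI, raised in both strains. As a hypothesis, a raised HAA1 may raise its targets. The median of 7 further targets relative to chromosomes was 1.18 in A9 and 0.97 in A14, both above all matched random lists, and at most 0.065 in the other strains. Values of NRE1 and YLR297W had been seen before the targets were listed, and the 5 others had medians of 1.18 and 0.97 too. Members differed: 4 of the 7 in A9 and 3 in A14 were at 1 or more, among them NRE1 at 1.75 and 2.24 and TPO3 at 1.18 and 1.16, while HRK1 was at 0.18 and 0.39, COM2 at 0.10 and 0.39 and YLR297W at 0.48 and -0.14. HAA1 itself was at 1.05 and 0.90 over WT2; another cause of Haa1 activity in these strains was not tested. The same reasoning for HAP4, a regulator of respiration on chromosome XI, raised in A10 and A15, was not borne out, since it failed in A15. HAP4 was at 2.18 and 0.56 over WT2, but the respiratory chain in A15 was at -0.36. HAP4 was also at 0.89 in A9, where chromosome XI lay at -0.11, and at 1.12 in A13. In A13 chromosome XI lay at 0.26, below the threshold of 0.3 but above all matched random lists. HAP4 was at -0.32 in A2, -0.21 in A3 and 0.27 in A14. Its sign was that of the respiratory chain median in each strain but A15, though that median was near 0 in A13 (0.01). A relation of HAP4 to respiration apart from the gain of chromosome XI was not tested.

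In A13, chromosomes II, VIII, XI and XIII had medians of 0.27, 0.23, 0.26 and 0.19, below those of raised chromosomes. Windows of 21 neighbouring genes lay above 0.1 in at least 94.3% of cases on each, which argues against a gain of part of a chromosome. Chromosome I of the same array was at 1.51 times the others, which argues against ratios compressed on this array. The gain of chromosome II was 0.417 of that of chromosome I, and a mixture of cells with different chromosomes may give this, but any fraction would be allowed, so it cannot be told apart. Chromosomes IX, III and XII of A15, at 0.12, 0.11 and 0.10, were also intermediate, and these explanations were not tested for them. No DNA measurement was analysed here.

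Ribosomal protein genes were lower in 7 of 7 strains. A high WT1 value alone is argued against by the chromosome-centred mean of -0.23 over WT2 without WT1 (camera, adjusted p 4.54e-13; adjusted p = 0.877 with an estimated correlation). A dye bias that follows intensity is argued against by medians below the central 95% of matched lists in 6 of 7 strains. A joint fall with ribosome biogenesis, as in slow growth, is argued against in A2, A3, A13 and A15, where biogenesis genes exceeded matched lists. In A10 and A14 the biogenesis genes lay below them at -0.38 and -0.14, beside ribosomal proteins at -0.38 and -0.18. A joint fall stays open in these 2 strains, and in A9, where biogenesis genes lay within matched lists at -0.03. WT1, with the same dyes, had a median of 0.01, and the chromosome-centred difference from it was -0.25, which argues against a dye effect common to all arrays. Cross-hybridisation was examined only by leaving out near-identical copies, where the difference from WT1 was -0.20 before and after, and otherwise stays open. Those copies were picked by gene name, as pairs ending in A and B and the PAU genes, without comparing sequences. Red saturation, in 18 to 101 gene spots per strain array against 9 on WT1, was not tested as a cause.

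Transcripts of large complexes could be held back when their genes lie on raised chromosomes. Relative to chromosomes, members on raised chromosomes minus members elsewhere, with at least 3 such members per strain, averaged 0.0724 for ribosomal proteins (6 strains, exact sign-flip p = 0.0312, adjusted 0.156), 0.102 for RNA polymerase I and III (4 strains, exact p = 0.5), 0.176 for the proteasome (4 strains, exact p = 0.125, the smallest possible), 0.0782 for the respiratory chain (6 strains, exact p = 0.125) and 0.0988 for the mitochondrial ribosome (6 strains, exact p = 0.0625). By this measure, set in advance, the lowest strain was above the bound of -0.1 for 4 lists (0.0078, 0.0842, -0.0799 and -0.0159 for ribosomal proteins, proteasome, respiratory chain and mitochondrial ribosome) and below it for RNA polymerase I and III (-0.21). But bright genes on raised chromosomes exceed the chromosome median (1.80 against 1.65 times the other chromosomes), so this bound was biased, and members were also matched to other genes on intensity and chromosome state, a version added after the first values were seen. Matched differences were -0.0151, -0.0231, 0.0234, -0.0341 and 0.0075, in the first order, with adjusted exact p of 0.906 in each. Lowest strains were at -0.137, -0.256, -0.0561, -0.199 and -0.138, so the bound held both ways for the proteasome alone. The test could not have called holding back in any list. Its smallest possible exact p, 0.0312 with 6 strains and 0.125 with 4, could not pass 0.05 after adjustment over the lists. Members held back in full would lie lower by the whole gain of their chromosomes, whose medians were at least 0.32. No list reached that in any strain, which argues against full holding back. A smaller effect stays open, for the proteasome only within the bound of -0.1.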
